A study of Mus musculus with 18 samples.

How the data were processed

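The series measured gene expression in 2 cell types sorted by flow cytometry from the bone marrow of C57BL/6 mice, monocytes with high surface Ly-6C and neutrophils. The controls carried floxed Zeb2 alleles alone. The mice labelled Zeb2-deficient carried the same alleles with Mx1-Cre, a recombinase that interferon switches on. The controls lacked Cre, so effects of Cre and of Zeb2 loss cannot be told apart here. Both genotypes received poly(I:C), a double-stranded RNA mimic that induces interferon, as 2 injections of 150 µg within 48 h, and marrow was taken 3 weeks later. For each cell type there were 4 arrays of poly(I:C) controls, 4 arrays labelled Zeb2-deficient and 1 array of an untreated control, 18 arrays in all. The labels do not say that the arrays of a group came from separate animals, so each p-value measures the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

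Total RNA was extracted with the RNAqueous-Micro kit and made into biotin-labelled target with the Ovation PicoSL kit, per the labels' protocols. The platform was the Affymetrix Mouse Gene 1.0 ST array, per the header of the probe annotation. The deposited values are log2 intensities summarised per probe set with RMA, per the submitters' processing notes. The software and version behind RMA, and its background step, are not given in the sources used here. The log2 scale was checked on the values, which ran from 1.05 to 13.5 with array medians of 4.81 to 4.92.

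Of 30177 probe sets, 21789 had 1 gene symbol, 1621 had several and 6767 had none, and only the first kind entered the tests of genes. They named 19938 genes, and 99.58% of the genes matched a gene identifier in the reference table. For the 999 genes with several probe sets, the one with the highest mean over all arrays was kept. A gene was tested if its value exceeded the array's 40th percentile in at least 4 of the 18 arrays, which left 13387 genes. Probe sets of near-identical relatives, such as the stefins Stfa3 and Cstdc6, were not told apart here. The probe set of Zeb2 summarises the whole transcript, and the labels do not give the deleted part, so the Zeb2 level does not check the deletion.

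Groups were compared with limma 3.58.1 in R 4.3.3, in a group-means model over all 18 arrays with a variance trend and 12 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. The contrasts were labelled Zeb2-deficient minus poly(I:C) control in each cell type, the difference between those changes, and control monocytes minus control neutrophils. The single untreated arrays stayed out of every test. All adjusted p-values below are two-sided and come from limma or, for gene lists, from its camera test with a preset correlation of 0.01 and adjustment over the 30 lists. Camera was repeated with a correlation estimated from the data, and fry, which asks whether the genes of a list move one way without comparing them with other genes, was run beside it. Counts of changed list members are over all genes tested, with the count adjusted over the list alone beside them.

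The groups, tests, alternatives, gene lists and naming rule were fixed before the data were examined. The 30 lists held 770 symbols, of which 605 were tested. They covered cells: Ly-6C(hi) monocytes, Ly-6C(low) monocytes, mature neutrophils with secondary granules, primary granules and promyelocytes, eosinophils, mast cells and basophils, macrophages, conventional dendritic cells with MHC class II, plasmacytoid dendritic cells, B cells, T and NK cells, erythroid cells, megakaryocytes and platelets, and stem and progenitor cells. They also covered programmes: cell cycle, interferon-stimulated genes, inflammatory cytokines, chemokine receptors and adhesion, Fc, complement and scavenger receptors, lysosome, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, dissociation stress, myeloid transcription factors, Id and E proteins, TGF-beta and BMP signalling, epithelial genes repressed by Zeb factors, and mesenchymal genes. Some genes stand in several lists. The genes named are Zeb2, the 10 highest and 10 lowest changes past the threshold with no overlap between the groups' arrays, the 10 smallest p-values of the difference between cell types, up to 4 members with the largest change of each list that passed, and up to 2 with the smallest p of every other list. Symbols that begin or end like clone, predicted or small RNA names were left out of the highest and lowest, which also drops Mirt2, a long non-coding RNA.

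Arrays of different groups were checked for shared deviations from their group means. Control and deficient arrays with the same number, within a cell type, correlated at 0.183 to 0.428 in 6 of 6 pairs. Only 3 of the 6 were closer than the other control and deficient pairs of their arrays within the sets described next. Pairing by number is therefore not shown by the values, and the labels do not state it. A wider split of the arrays held all 6 pairs. The poly(I:C) controls 1 and 2 and the deficient arrays 1 and 2, called set A, deviated together, against controls 4 and 5 and deficient 3 and 4, called set B. The untreated arrays are alone in their groups and have no deviation to compare, so they were placed in set A by sample order only. Between groups, 44 of 48 pairs within a set correlated above 0.1, and all 48 pairs across sets correlated below 0, from -0.344 to -0.0357. The deviations of a group sum to 0, so correlations above 0 within sets force ones below 0 across sets on average. The pairs across sets are therefore not separate evidence. The sets follow the order of the samples in the series. They were found after the data were seen, the labels do not name them, and fits with the set as a block and within each set were added then.

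Simulated data were drawn for the 13387 genes with known changes added. In the monocyte comparison, 31.3% of genes changed by 0.5 on the log2 scale were recovered, 88.1% of those changed by 1.0 and all of those changed by 2.0. For neutrophils the shares were 34.3%, 91.0% and 98.5%, for the difference between cell types 5.97%, 68.7% and 97.0%, and for the cell type comparison 32.8%, 94.0% and 98.5%. The false share of calls was 6.41%, 5.10%, 2.56% and 5.66% in that order, and 1 shifted list was found in each with 0 others called. Each gene was drawn independently, without array sets, shared deviations of arrays or correlation within lists. These shares therefore do not measure false calls of genes or lists on the real arrays.

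Alternatives covered the filter, the probe set per gene, quantile normalization or median centring of the arrays, variance moderation, array weights, the arrays fitted, the untreated controls, blocks for the replicate number (fixed, or random with statmod 1.5.0), stricter thresholds, and leaving out each array. An offset for linear values was not run because the values are on a log2 scale. Other splits of the arrays into groups of the same sizes were counted, all 35 of each pair of groups and 100 drawn for the difference between cell types. Where an array of a group of 4 stood apart was tested with Dixon's ratio of its gap to the group's range. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.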

Results

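Expression was measured on 18 arrays of sorted mouse bone marrow cells, 9 of Ly-6C(hi) monocytes and 9 of neutrophils. Each cell type had 4 poly(I:C)-treated controls, 4 poly(I:C)-treated samples labelled Zeb2-deficient and 1 untreated control. Zeb2 encodes a zinc-finger repressor. The comparisons ask which genes differ when Zeb2 is conditionally deleted in each cell type, and whether the cell types respond alike.

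Zeb2 itself (probe set 10482448) was higher in monocytes than in neutrophils, and the labelled deletion was not visible as a loss of signal in both. In monocytes the poly(I:C) controls read 10.08, 9.88, 9.88 and 9.86 (log2), and the samples labelled deficient 9.75, 9.84, 9.46 and 8.74. The group means were 9.92 ± 0.10 (SD, n = 4) and 9.45 ± 0.50 (SD, n = 4), a change of -0.48 ± 0.24 (SE) with adjusted p = 0.272. In neutrophils the controls read 7.19, 6.86, 7.54 and 7.40, and the samples labelled deficient 7.72, 7.10, 7.85 and 8.25. Their means were 7.24 ± 0.30 (SD, n = 4) and 7.73 ± 0.48 (SD, n = 4), a change of 0.49 ± 0.24 (SE) with adjusted p = 0.972. The neutrophil values therefore ran against the label, and directions below are for samples labelled Zeb2-deficient, whatever their Zeb2 level. The untreated controls read 9.75 in monocytes and 6.66 in neutrophils. The monocyte change was -0.18 in array set A and -0.77 in array set B (adjusted p = 0.0350 in set B), and adjusted p was 0.0772 with the set as a block. The changes differed between the cell types by -0.97 ± 0.33 (SE), with adjusted p = 0.160 and, with the set as a block, 0.0232.

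**Figure D1:**
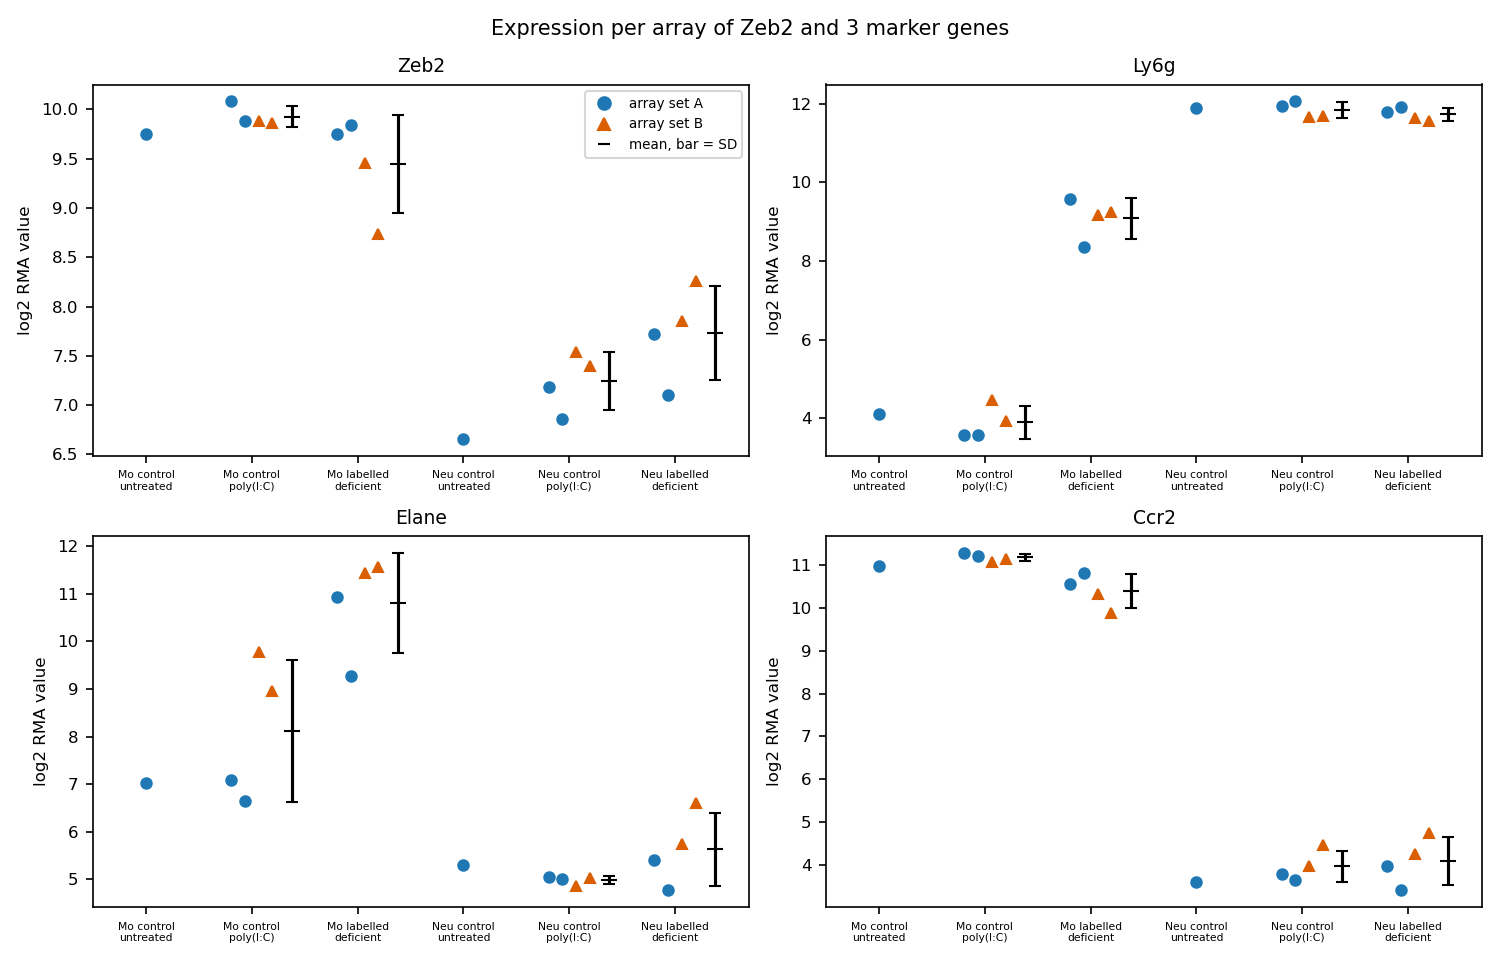
Log2 expression of Zeb2, Ly6g, Elane and Ccr2 in each array, by group, with symbols for the array set (untreated arrays by sample order only) and bars for the mean and SD of groups of 4. Mean Ly6g was 3.90 in control monocytes and 9.09 in monocytes labelled Zeb2-deficient, and Zeb2 overlapped between the neutrophil groups.

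Control monocytes and control neutrophils were compared to describe the sorted populations. Monocytes were higher in Fn1 (fibronectin) by 7.52 ± 0.21 (SE, 184-fold, adjusted p = 1.11e-14) and in the chemokine receptor Ccr2 by 7.20, or 147-fold. Next came Ms4a6b, Ms4a6c, Ly86, Ms4a4c, the transglutaminase subunit F13a1, Ifi209, Lgals1 and S100a4, by 6.19 to 7.10. Neutrophils were higher in the surface marker Ly6g (-7.94 ± 0.22 SE, 245-fold, adjusted p = 1.17e-14), the gelatinase Mmp9 (-7.51), the chemokine receptor Cxcr2 (-7.26) and Retnlg (-7.26). Stfa3, Il1f9, Ceacam10, Scrg1, AA467197 and the decoy receptor Il1r2 followed, at -7.21 to -6.15, and among them the non-coding RNA Mirt2 (-6.61), chosen after its values were seen. Ly6g in monocytes (3.90) and Ccr2 in neutrophils (3.97), like several others of these genes, lay below the 40th percentile of the arrays (4.30 to 4.37 and 4.41 to 4.46), so such folds are lower bounds. In all, 7846 of 13387 genes differed, 3998 higher in monocytes and 3848 higher in neutrophils, and 2762 of them by at least 2-fold (1804 and 958). Arrays did not overlap for 7010 of those genes, and for 7525 of all genes (56.2%, chance 2.86%). With the array set as a block 7616 genes differed, and 6142 and 6247 within sets A and B.

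Lists followed the sort, and 12 of 30 passed, but 0 did with an estimated correlation. All 25 mature neutrophil and secondary granule genes were higher in neutrophils (median -4.00, adjusted p = 1.01e-16; 0.136 with an estimated correlation). Of 23 Ly-6C(hi) monocyte genes, 19 were higher in monocytes (median 4.21, adjusted p = 3.42e-13, and 0.137 with an estimated correlation). Adjusted over the list alone the counts were also 25 and 19. Monocytes were higher in 40 of 42 cytosolic ribosomal protein genes (41 adjusted over the list alone). The median was 1.41 (adjusted p = 0.136 with an estimated correlation), and the highest were Rpl10a, Rps18, Rps20 and Rps19. They were also higher in 30 of 37 oxidative phosphorylation genes (median 0.69, Ndufb5 and Atp5a1 the most, 0.277 with an estimated correlation). They were higher in 30 of 43 cell cycle genes with 1 lower (median 0.72, Mcm6 the most), and in 18 of 27 lysosome genes with 4 lower (median 0.92), both at 0.468 with an estimated correlation. The proteases Ctsc and Ctss led the lysosome genes, while Cd63 and Ctse were lower. The MHC class II genes Cd74, H2-DMa and H2-Aa, with Naaa, led the conventional dendritic cell list (13 of 21 higher, 4 lower, median 0.79, 0.277 with an estimated correlation). Ifi203, Ifi205, Mx1 and Mx2 led the interferon-stimulated list (20 of 36 higher, 8 lower, median 0.72, 0.653 with an estimated correlation). Neutrophils were higher in the megakaryocyte list (7 of 13, median -0.63, Cd9 and Clec1b) and the mast cell and basophil list (5 of 8, median -0.35, the histidine decarboxylase gene Hdc at -5.33). They were also higher in the inflammatory cytokine list (15 of 25 with 6 higher in monocytes, median -0.49, Il1b, Ptgs2 and Cxcl2) and the Zeb-repressed epithelial list (7 of 19, median -0.27, Cd24a). With an estimated correlation adjusted p was 0.465 for cytokines and 0.277 for the other 3 of these lists. The interferon list did not pass with the array set as a block (adjusted p = 0.169), and the epithelial and inflammatory cytokine lists did not after quantile normalization. Adjusted over the list alone, the members higher and lower numbered 30 and 0 for oxidative phosphorylation, 31 and 1 for cell cycle, 18 and 4 for lysosome, 13 and 5 for dendritic cells, 20 and 9 for interferon and 6 and 15 for cytokines. There were 7, 5 and 5 lower for the megakaryocyte, mast cell and epithelial lists.

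The other 18 lists did not pass between the control cell types. Erythroid genes had a median of -0.35 (adjusted p = 0.101), B cell genes -0.23 (0.101), glycolysis -0.32 (0.101), chemokine receptors and adhesion -0.38 (0.173). T and NK cell genes had -0.26 (0.237), dissociation stress -0.47 (0.366) and TGF-beta and BMP signalling -0.13 (0.444). Cholesterol synthesis had -0.125 (0.493), Id and E proteins 0.15 (0.493), eosinophil genes -0.41 (0.584) and macrophage genes 0.094 (0.617). Primary granule genes had 1.18 (0.634), stem and progenitor genes 0.12 (0.634) and Ly-6C(low) genes 0.35 (0.651). The median and the mean or test differed in sign for plasmacytoid dendritic cell genes (median -0.025, mean 0.48, adjusted p = 0.487), mesenchymal genes (-0.20, 0.73, 0.624), Fc, complement and scavenger receptors (-0.22, 0.012, 0.651) and myeloid transcription factors (-0.075, 0.097, 0.967).

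In monocytes labelled Zeb2-deficient, genes high in neutrophils were among those that rose most. Retnlg, a resistin-like secreted protein, rose by 5.55 ± 0.24 (SE, 46.8-fold, adjusted p = 5.88e-11), from 5.04 to 10.6 on the log2 scale. Ly6g rose by 5.18 ± 0.22 (SE, 36.4-fold, adjusted p = 5.88e-11), from 3.90 ± 0.42 (SD, n = 4) to 9.09 ± 0.53 (SD, n = 4), against 11.8 in control neutrophils. The stefin Stfa3, the chitinase-like Chil1 and lactoferrin (Ltf), a secondary granule protein, rose by 4.78, 4.73 and 4.28. Of 25 mature neutrophil and secondary granule genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 2.53 (adjusted p = 7.78e-34; 0.0227 with an estimated correlation). Of 14 primary granule and promyelocyte genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 2.33 (adjusted p = 2.88e-19; 0.0943 with an estimated correlation). They included Nkg7, also a cytotoxic lymphocyte gene (3.85), Ms4a3 (3.29), the lectin Fcnb (3.13) and neutrophil elastase, Elane, which went from 8.11 to 10.8 against 4.98 in control neutrophils (2.69 ± 0.58 SE, adjusted p = 0.00707). Cxcr2 (3.66) and the granulocyte transcription factor Cebpe (2.29) rose as well. The remaining highest changes were the resistin-like Retnla (5.43), the lectin Clec4b2 (3.99), the interleukin Il1f9 (3.98) and the claudin Cldn1 (3.98). Retnla and Clec4b2 are not high in neutrophils, reading 4.10 and 5.24 in control neutrophils against 8.44 and 8.92 here. In control monocytes Ly6g, Retnla, Stfa3, Il1f9 and Cldn1 lay below the 40th percentile of the arrays (4.30 to 4.37), so their changes and folds are lower bounds. These genes also differed between array sets among control monocytes, set B lying above set A by a median of 0.95 for the primary granule list and 0.57 for the mature neutrophil list. Within sets A and B the genotype medians were 2.27 and 2.14 for the former and 2.41 and 2.09 for the latter.

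The cell cycle list also passed in the upward direction. Of 43 cell cycle genes 15 rose and 0 fell (34 and 0 adjusted over the list alone), all 43 lay above 0, and the median was 0.59 (adjusted p = 8.85e-23; 0.231 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 rose by 1.28 ± 0.24 (SE, adjusted p = 0.00268), cyclin Ccne2 by 1.26, and the helicase subunits Mcm2 and Mcm6 by 1.23 and 1.12. The cell cycle median was 0.28 in set A and 0.92 in set B. In set A alone adjusted p was 0.186 for Rrm2, 0.0631 for Ccne2, 0.0503 for Mcm2 and 0.132 for Mcm6. The mast cell and basophil list passed with 2 of 8 genes risen and 0 fallen (3 and 0 adjusted over the list alone). The receptor Kit rose by 2.01 and Hdc by 1.35, with a median of 0.087 (adjusted p = 0.0195; 0.280 with an estimated correlation). The list did not pass without monocyte control replicate 2. Hdc read 10.7 in control neutrophils against 5.39 in control monocytes, so its rise is not told apart from that of the neutrophil genes. Mcpt8 was at 1.41 (adjusted p = 0.0645) and Slc18a2 at 0.15 (0.570). Glycolysis passed with 3 of 19 risen and 1 fallen, also adjusted over the list alone, and a median of 0.22 (adjusted p = 0.0154; 0.311 with an estimated correlation). The glucose transporter Slc2a3 rose by 2.31, the hexokinase Hk3 by 0.87 and Pgk1 by 0.43, while Ldha was at 0.53 (adjusted p = 0.165). With the replicate number as a block limma gave adjusted p = 0.0357 for Ldha. Slc2a3 read 10.4 in control neutrophils against 4.79 in control monocytes, so its rise too is not told apart from that of the neutrophil genes. Cholesterol synthesis passed narrowly with 3 of 18 risen and 0 fallen, also adjusted over the list alone, and a median of 0.13 (adjusted p = 0.0468; 0.280 with an estimated correlation; 0.0631 after quantile normalization). Fdps rose by 1.16, Hsd17b7 by 0.69 and Sc5d by 0.66, and Insig1 was at -0.47 (adjusted p = 0.168). Epithelial genes that Zeb factors repress passed with 4 of 19 risen and 0 fallen, also adjusted over the list alone, a median of 0.032 and a mean of 0.31 (adjusted p = 0.0116; 0.252 with an estimated correlation; 0.151 under the stricter filter). The 4 were Cd24a, a glycoprotein that neutrophils also carry (1.99 ± 0.15 SE, adjusted p = 1.86e-07), the desmosomal Dsp (1.29), keratin Krt18 (1.02) and the tight junction gene Marveld2 (0.94). The medians within sets A and B were 0.21 and 0.0082 for the mast cell list, 0.21 and 0.34 for glycolysis, 0.20 and 0.037 for cholesterol synthesis, and 0.13 and -0.0087 for epithelial genes.

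Monocyte genes fell. Of 23 Ly-6C(hi) monocyte genes, 7 fell and 0 rose (17 and 0 adjusted over the list alone), 22 lay below 0, and the median was -0.76 (adjusted p = 9.36e-10; 0.231 with an estimated correlation). Tmem176b fell by 1.32 ± 0.18 (SE, adjusted p = 1.45e-04), the fractalkine receptor Cx3cr1 by 1.17 ± 0.27 (SE, adjusted p = 0.0110) and the chemokine Ccl9 by 0.87, while the Fc receptor Fcgr1 was at -0.91 (adjusted p = 0.0622). The median was -0.35 in set A and -1.01 in set B. Elsewhere, among genes whose groups of arrays did not overlap, the lowest changes were the prostaglandin dehydrogenase Hpgd (-1.99 ± 0.38 SE, adjusted p = 0.00271), the transporter Abca9 (-1.84), the lectin Cd209a (-1.49), Nlrp1c-ps (-1.42), Kctd12b (-1.40), the sterol hydroxylase Cyp27a1 (-1.37), the mannose receptor Mrc1 (-1.35) and Rgs1 (-1.30). Interferon-stimulated genes had a median of -0.48, with 33 of 36 below 0, 2 fallen and 0 risen (9 and 0 adjusted over the list alone). Camera gave adjusted p = 5.34e-07, 0.327 with an estimated correlation and 0.0576 by fry. The interferon median was -0.15 in set A and -0.72 in set B, and among control monocytes this list lay 0.26 higher in set B than in set A. Lgals3bp fell by 0.83 (adjusted p = 0.0448; 0.149 when only the arrays compared were fitted), and Oas1a, Gbp3 and Rtp4 were at -0.94, -0.84 and -0.82 (adjusted p = 0.0884, 0.0709 and 0.239). With the replicate number as a block limma gave adjusted p = 0.00929 for Oas1a and 0.0274 for Rtp4. Dissociation stress genes had a median of -0.37, with 6 of 21 fallen and 0 risen (10 and 2 adjusted over the list alone). Camera gave adjusted p = 9.23e-04 and 0.311 with an estimated correlation. The stress factor Atf3 fell by 1.46 and Nr4a1 by 0.92, and Fosb and Ier3 were at -1.20 and 0.99 (adjusted p = 0.0630 and 0.0840). For Fosb and Ier3 limma gave adjusted p = 0.00450 and 0.0112 with the replicate number as a block. Among control monocytes this list lay 0.47 higher in set B than in set A. The lysosome list had a median of -0.24, with 3 of 27 fallen and 2 risen (6 and 2 adjusted over the list alone). Camera gave adjusted p = 0.0403, 0.563 with an estimated correlation, 0.217 by fry and 0.0517 after quantile normalization. The lipase Lipa fell by 0.87 and Ctsa by 0.77, Cd63 rose by 3.15, and Lgmn was at -0.78 (adjusted p = 0.0889). Cytosolic ribosomal protein genes had a median of -0.092 with all 42 below 0 and 0 called by limma, also adjusted over the list alone (adjusted p = 0.0403, then 0.563 with an estimated correlation, 0.207 by fry and 0.125 after quantile normalization). Rpl14, Rpl22, Rpl24 and Rplp2 were at -0.28 to -0.21. The medians within sets A and B were -0.28 and -0.56 for dissociation stress, -0.12 and -0.35 for lysosome, and -0.11 and -0.073 for ribosomal proteins. These falls stand beside the rise of mature neutrophil genes in the same group of arrays, with a median of 2.53.

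Transcription factors moved in both directions. Myb, a progenitor factor, rose by 2.09 ± 0.29 (SE, adjusted p = 1.39e-04), Erg by 1.68, and Zeb1, the relative of Zeb2, by 1.31 ± 0.18 (SE, adjusted p = 1.33e-04). The inhibitor Id2 rose by 0.88 and the E protein Tcf4 fell by 0.87 (adjusted p = 0.00395 and 0.00252), with set A alone at adjusted p = 0.154 and 0.181. Their lists did not pass. Myeloid transcription factors had a median of -0.18 with 4 of 40 risen and 4 fallen (adjusted p = 0.214), mesenchymal genes -0.14 with 1 of 15 risen and 1 fallen, Itgav (adjusted p = 0.396), and Id and E proteins 0.099 with 1 of 6 each way (adjusted p = 0.631). TGF-beta and BMP signalling had -0.15 with 2 of 30 risen and 3 fallen (adjusted p = 0.157), Bmpr1a being among the risen. Stem and progenitor genes had a median of -0.023 but a mean of 0.39, with 5 of 18 risen and 1 fallen and a test in the upward direction (adjusted p = 0.0575).

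Among the remaining lists in monocytes, chemokine receptors and adhesion had a median of 0.025 with 10 of 32 risen and 2 fallen (adjusted p = 0.0703), conventional dendritic cell genes -0.33 with 2 of 21 risen and 4 fallen (0.0703), and inflammatory cytokines -0.085 with 1 of 25 risen and 4 fallen, among them Ccl6 (0.0691). Fc, complement and scavenger receptors had -0.22 with 5 of 39 risen, Trem1 by 2.16, and 7 fallen (0.112), eosinophil genes 0.14 with 2 of 7 risen and Adgre4 fallen (0.135), and Ly-6C(low) genes -0.079 with 2 of 15 risen, Cd9 and Lair1, and 3 fallen (0.733). Erythroid genes had 0.031 with Tfrc alone of 11 risen (0.389) and oxidative phosphorylation -0.027 with 0 of 37 called and a test in the upward direction (0.977), Cox5a and Uqcrfs1 being at 0.23 and -0.21. The medians and means differed in sign for megakaryocyte genes (-0.12 and 0.048, Cd9 risen and F2rl2 fallen of 13, 0.291), B cell genes (-0.062 and 0.14, Cd24a and Cd37 risen of 14, 0.630), T and NK cell genes (-0.040 and 0.26, Nkg7 and Cd5 risen of 13, 0.775) and plasmacytoid dendritic cell genes (-0.057 and 0.019, 3 of 18 each way, Atp1b1 risen, 0.953). So they did for macrophage genes (-0.047 and 0.16, 3 of 19 risen, Cd81 and Slc40a1 among them, and 2 fallen, 0.973). Adjusted over the list alone, the members risen and fallen numbered 10 and 6 for chemokine receptors, 2 and 7 for dendritic cells, 6 and 16 for Fc receptors, 4 and 10 for transcription factors, and 2 and 5 for TGF-beta. They numbered 3 and 4 for Ly-6C(low), 4 and 5 for plasmacytoid cells, 3 and 3 for macrophages, and 1 and 2 for both megakaryocyte and mesenchymal genes. The other lists kept their counts.

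In all, 1010 of 13387 genes changed in monocytes, 684 up and 326 down, and 304 of them by at least 2-fold (266 up, 38 down). The median of all genes was -0.034, and the groups' arrays did not overlap for 732 of the called genes and for 1344 of all (10.04%, chance 2.86%). Unadjusted p was under 0.05 for 2699 genes, with 669.4 expected by chance. All 1010 had the same sign in both array sets, which choosing genes by calls over both sets favours, with 215 genes called within set A, 1724 within set B and 1749 with the set as a block, and with array weights 1613. The replicate number as a block kept 596 of the 1010 calls and called 688 genes. It ended the calls of Hsd17b7 (0.77 ± 0.20 SE with the block, adjusted p = 0.0558), Lipa (-0.78 ± 0.21, 0.0671), F2rl2 (-0.66 ± 0.21, 0.105) and Krt18 (0.83 ± 0.29, 0.139), and of the cholesterol synthesis list. Without the block they were 0.69 ± 0.19, -0.87 ± 0.21, -0.58 ± 0.17 and 1.02 ± 0.30 (SE), so for these genes changes and SEs moved little, while the block leaves fewer degrees of freedom. Those calls, and the calls of Lgals3bp, Ctsa, Itgav, Fdps, Sc5d, Cd5 and Cd37, also ended when single arrays were left out. The block also brought 5 named genes past the threshold, with SEs at 0.42 to 0.58 of those without it. They were Fosb (-1.23 ± 0.18 SE, adjusted p = 0.00450), Ier3 (0.79, 0.0112), Ldha (0.55, 0.0357), Oas1a (-0.97, 0.00929) and Rtp4 (-0.76, 0.0274). Control 5 and deficient 3 have no partner of the same number, so the block rests on 3 same-numbered pairs. Without deficient replicate 2 the count was 2001, without deficient replicate 3 it was 621 and without deficient replicate 4 it was 620. Of the 12 lists that passed, only the mature neutrophil list kept its call with an estimated correlation, and 9 kept theirs by fry. With the array set as a block 14 of the 30 lists passed in monocytes.

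**Figure D2:**
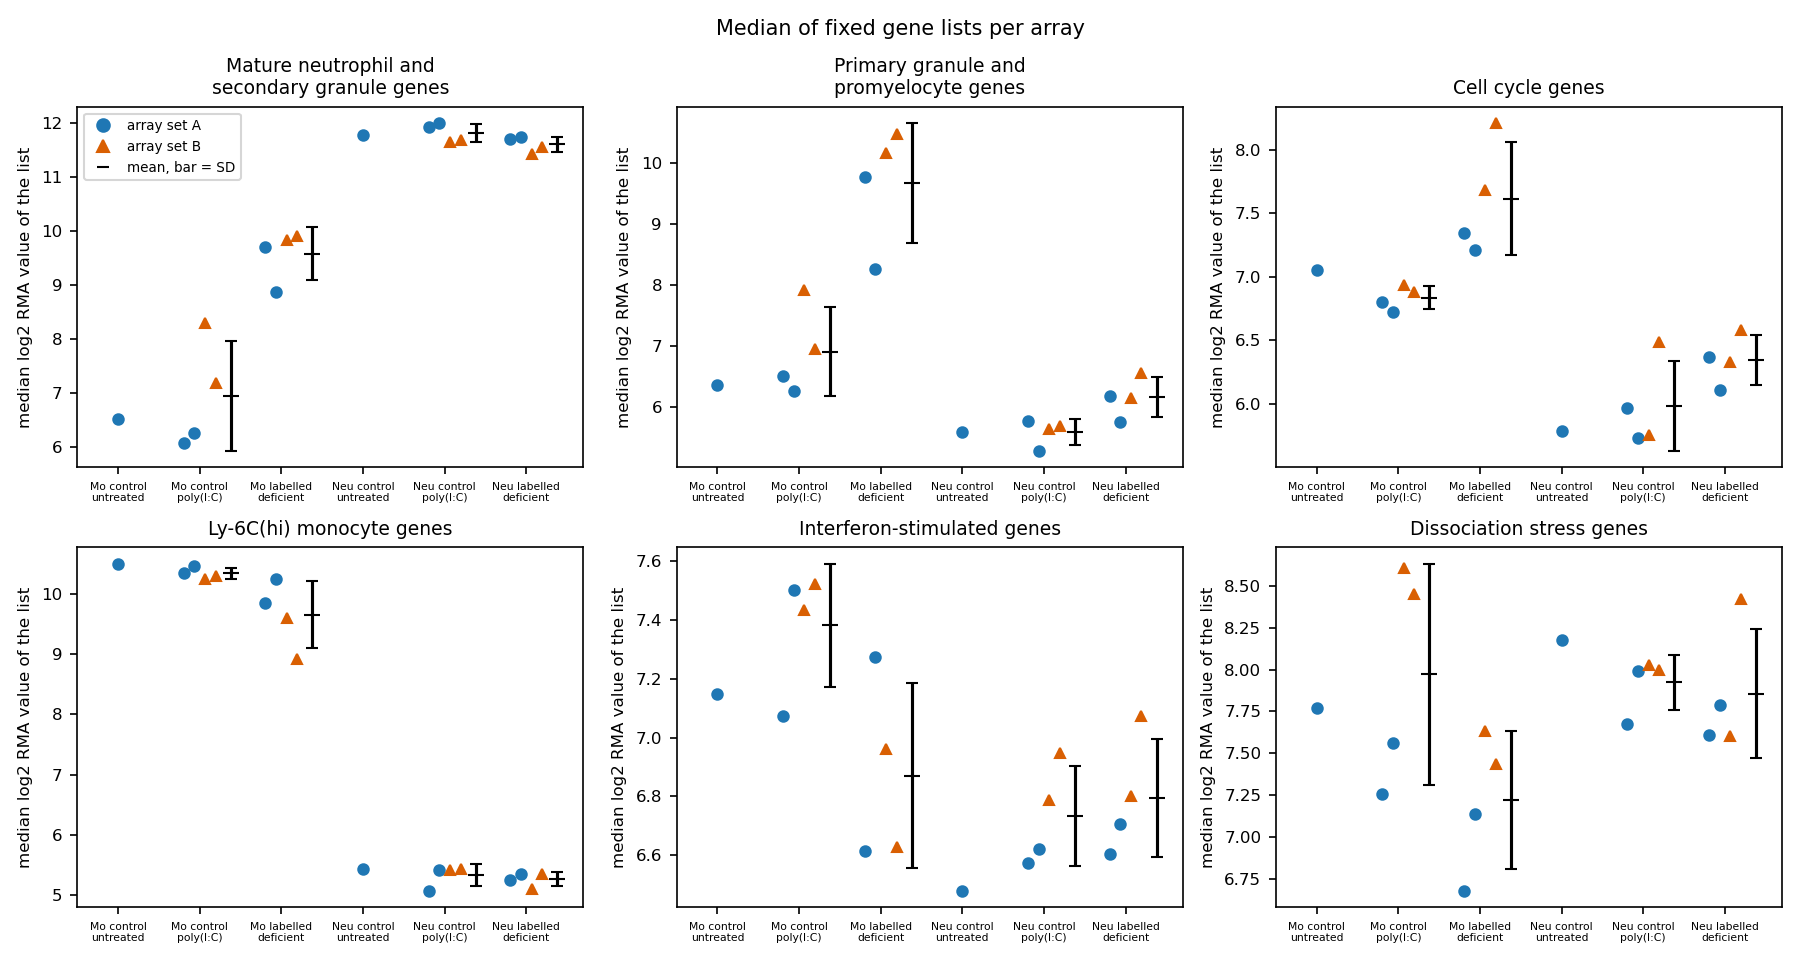
Median log2 expression of 6 gene lists in each array, by group, with symbols for the array set (untreated arrays by sample order only) and bars for the mean and SD of groups of 4. The mature neutrophil list averaged 6.95 in control monocytes, 9.58 in monocytes labelled Zeb2-deficient and 11.8 in control neutrophils, and the primary granule list 6.91, 9.68 and 5.6.

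Few genes changed in neutrophils labelled Zeb2-deficient. The steroid dehydrogenase Hsd17b2 rose by 2.36 ± 0.22 (SE, 5.14-fold, adjusted p = 3.61e-05), from 4.72 to 7.08, and the stefin-like Cstdc6 by 2.20 ± 0.35 (SE, adjusted p = 0.00910). The lectin receptor Clec4n rose by 1.80, the dynein Dnah6 by 1.49, the macrophage growth factor Csf1 by 1.48 ± 0.20 (SE, adjusted p = 0.00258) and the transcription factor Egr2 by 1.45. Pdlim1 (1.23), Crip1 (1.22), the Rag GTPase Rragd (1.11) and Arhgap5 (0.93) rose too. The opioid precursor Penk fell by 1.21 ± 0.14 (SE, adjusted p = 4.63e-04) and the nucleotide enzyme Adss by 0.61. The interferon-inducible Ifi203 was called at 0.89 (adjusted p = 0.0304), a call that ended without any 1 of the 8 arrays. Ifi203 and Arhgap5 lay below the 40th percentile of the arrays in control neutrophils. Mean Penk (4.325) lay below it in neutrophils labelled Zeb2-deficient (4.40 to 4.50). The sizes of these changes are lower bounds. In total 16 of 13387 genes changed, 14 up and 2 down, 10 of them by at least 2-fold (9 and 1). The arrays of the groups did not overlap for each of the 16, and for 459 of all genes (3.43%, chance 2.86%), and unadjusted p was under 0.05 for 683 genes with 669.4 expected. All 16 had the same sign in both array sets, which choosing genes by calls over both sets favours. In set A 3 genes were called, in set B 14 and with the set as a block 27. The count was 9 when only the arrays compared were fitted, 8 without deficient replicate 1 and 9 without control replicate 4. The replicate number as a block kept 10 of the 16 calls and called 11 genes. It ended the calls of Cstdc6 (2.04 ± 0.32 SE with the block, adjusted p = 0.0971), Crip1 (1.39 ± 0.24, 0.148), Rragd (0.93 ± 0.14, 0.0839), Adss (-0.59 ± 0.13, 0.360) and Ifi203 (0.84 ± 0.18, 0.334). Without the block they were 2.20 ± 0.35, 1.22 ± 0.23, 1.11 ± 0.15, -0.61 ± 0.11 and 0.89 ± 0.16 (SE), so here too the changes and SEs moved little, with fewer degrees of freedom left. Leaving out single arrays ended those of Pdlim1, Crip1, Adss, Egr2, Cstdc6 and Ifi203.

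Neutrophil lists showed small shifts with 0 members called by limma, also adjusted over the list alone. Cell cycle genes had a median of 0.23, 36 of 43 above 0 (adjusted p = 6.76e-07; 0.610 with an estimated correlation), with Ect2 at 0.79, Ccna2 at 0.58, Top2a at 0.50 and Mcm7 at 0.46. Glycolysis had -0.18, 17 of 19 below 0 (adjusted p = 6.16e-04; 0.214 with an estimated correlation), with Ldhb, Pkm, Tpi1 and Ldha between -0.55 and -0.38, and in set A it was -0.018 (adjusted p = 0.165). Cholesterol synthesis had -0.19, 15 of 18 below 0 (adjusted p = 0.00330; 0.214 with an estimated correlation), with Hsd17b7, Nsdhl, Msmo1 and Sc5d between -0.50 and -0.42. Oxidative phosphorylation had -0.085 (adjusted p = 0.0222; 0.655 with an estimated correlation; 0.110 after quantile normalization), with Sdhc, Sdhd, Atp5b and Ndufa9 between -0.47 and -0.26, but -0.24 in set A and 0.040 in set B. These 4 of 30 lists passed. Of all lists, 0 did with an estimated correlation and 0 by fry, 5 did with the array set as a block, 8 did with the replicate number as a block, and 7 without deficient replicate 2 or without control replicate 5.

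The other lists did not pass in neutrophils. Ly-6C(low) genes had a median of 0.063 (adjusted p = 0.0510; Dusp16 0.69 and Itgax 0.77), inflammatory cytokines 0.13 (0.0648; Ccl4 0.56, Ptgs2 0.41) and T and NK cell genes 0.13 (0.0658; Lat 0.49). Primary granule genes had 0.22 (0.119; Gstm1 0.53, Ctsg 0.68), eosinophil genes 0.082 (0.119; Siglecf 0.53), stem and progenitor genes 0.061 (0.163; Cd93 0.41) and conventional dendritic cell genes 0.020 (0.216). Lysosome genes had -0.073 (0.246; Ctsc -0.62), mast cell genes 0.068 (0.361; Mcpt8 1.14), and mature neutrophil genes -0.072 (0.372; Hp -0.35, Cd177 -0.42). Interferon-stimulated genes had 0.063 (0.422; Ifi203 risen), megakaryocyte genes 0.012 (0.442), mesenchymal genes 0.057 (0.442) and Fc and scavenger receptors -0.082 (0.446; Clec4n risen, Scarb2 0.71). Ribosomal proteins had -0.046 (0.450), macrophage genes -0.074 (0.458), Id and E proteins 0.048 (0.572), Ly-6C(hi) genes -0.062 (0.601; Ms4a6c -0.58), dissociation stress -0.088 (0.709; Egr2 risen) and B cell genes -0.037 (0.931). The median and the mean differed in sign for erythroid genes (-0.0014 and 0.048, 0.442), myeloid transcription factors (-0.0016 and 0.046, Egr2 risen, 0.442), epithelial genes (-0.018 and 0.052, 0.442), chemokine receptors (-0.033 and 0.037, 0.450), TGF-beta signalling (-0.020 and 0.019, 0.572) and plasmacytoid dendritic cell genes (-0.0032 and 1.4e-05, 0.791). Adjusted over the list alone, 1 to 3 members were called in 8 of these lists and 0 in the others.

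The changes in the cell types were then compared directly. Retnlg differed by 5.55 ± 0.34 (SE) and Ly6g by 5.29 ± 0.31 (SE), each with adjusted p = 2.12e-08. Stfa3 (4.77), Chil1 (4.52), Il1f9 (3.90), AA467197 (3.75), Cldn1 (3.72), the interleukin receptor subunit Il18rap (2.68), Cd24a (2.02) and Ifit1bl2 (1.47) complete the 10 with the smallest p. Mature neutrophil genes differed by a median of 2.66, with 16 of 25 called higher and 0 lower (23 and 0 adjusted over the list alone; adjusted p = 5.27e-35; 0.0198 with an estimated correlation). Primary granule genes differed by 2.04, with 6 of 14 (11 adjusted over the list alone; adjusted p = 2.47e-13; 0.132 with an estimated correlation). Cell cycle genes differed by 0.34 (4 of 43 called higher, 10 adjusted over the list alone; Ccne1 1.32, Mcm2 1.26; adjusted p = 5.36e-09; 0.380 with an estimated correlation). Glycolysis differed by 0.45 (2 of 19, then 4; Slc2a3 2.45; adjusted p = 2.75e-05; 0.117 with an estimated correlation). Cholesterol synthesis differed by 0.38 (2 of 18 both ways of adjusting; Hsd17b7 1.19, Sc5d 1.08, the former at adjusted p = 0.0508 with genotype and number as a block, its change unmoved and its SE 0.29 against 0.27; adjusted p = 8.26e-04; 0.0906 with an estimated correlation). Ly-6C(hi) genes differed by -0.67 (Tmem176b alone of 23, 5 adjusted over the list alone; adjusted p = 4.29e-07; 0.307 with an estimated correlation). Interferon-stimulated genes differed by -0.50 (Ifi203 alone of 36, also adjusted over the list alone, at -1.50; adjusted p = 1.36e-06; 0.380 with an estimated correlation). Dissociation stress differed by -0.33 (Egr2 -1.62 and Atf3 -1.26 of 21, 4 adjusted over the list alone; adjusted p = 0.00293; 0.380 with an estimated correlation). Inflammatory cytokines differed by -0.29 (Il18 at -1.52 alone of 25, then 1 higher and 4 lower; adjusted p = 0.00424; 0.310 with an estimated correlation). Conventional dendritic cell genes differed by -0.31 (Cd24a higher and Cd209a lower of 21, then 1 and 3; adjusted p = 0.0163; 0.235 with an estimated correlation). The difference passed for 359 genes, 290 higher in monocytes and 69 lower, 259 of them by at least 2-fold. All 359 had the same sign in both array sets, which choosing genes by calls over both sets favours. In set A 72 genes were called, in set B 731 and with the set as a block 727. The count was 650 with array weights, 551 with all 5 controls and 904 without monocyte deficient replicate 2. Of the 10 lists that passed, the mature neutrophil list alone did with an estimated correlation, and 4 did by fry.

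Of the 20 lists whose difference did not pass, epithelial genes came closest, with a median of 0.093 (adjusted p = 0.0575). Mast cell genes were at 0.066, TGF-beta signalling at -0.21 and Ly-6C(low) genes at -0.20 (each 0.164), myeloid transcription factors at -0.13 (0.171), megakaryocyte genes at -0.30 (0.186), oxidative phosphorylation at 0.044 and ribosomal proteins at -0.059 (each 0.197), and chemokine receptors at 0.028 (0.228). Mesenchymal genes were at -0.16 (0.260), Fc receptors at -0.20, lysosome at -0.22 and stem and progenitor genes at -0.013 with a mean of 0.30 (each 0.270), T and NK cell genes at -0.097 with a mean of 0.10 (0.519) and B cell genes at -0.015 with a mean of 0.15 (0.550). Erythroid genes were at 0.065 and eosinophil genes at -0.0053 with a mean of 0.13 (each 0.689), macrophage genes at -0.055 with a mean of 0.24 and plasmacytoid genes at -0.015 with a mean of 0.019 (each 0.804), and Id and E proteins at 0.11 with a mean of -0.0048 (0.809).

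Across the 13387 genes the changes in the cell types were nearly unrelated, with Pearson's r = 0.0549 ± 0.0581 (jackknife SE over arrays) and Spearman's rho = 0.0425. Genes are not independent replicates. The neutrophil changes lay near chance, with 683 genes at unadjusted p under 0.05 by limma and 669.4 expected. A low r therefore cannot tell unlike responses from a neutrophil change too small to measure. No gene changed in the same direction in both, with 0.715 expected to rise in both by chance, and Ifi203 alone passed in both, falling by 0.61 in monocytes and rising by 0.89 in neutrophils, where with the replicate number as a block the change was 0.84 and adjusted p = 0.334. Of the 1010 genes called in monocytes, 500 had the same sign in neutrophils, under the same limit. Within set A r was 0.0407 and within set B 0.0763.

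**Figure D3:**
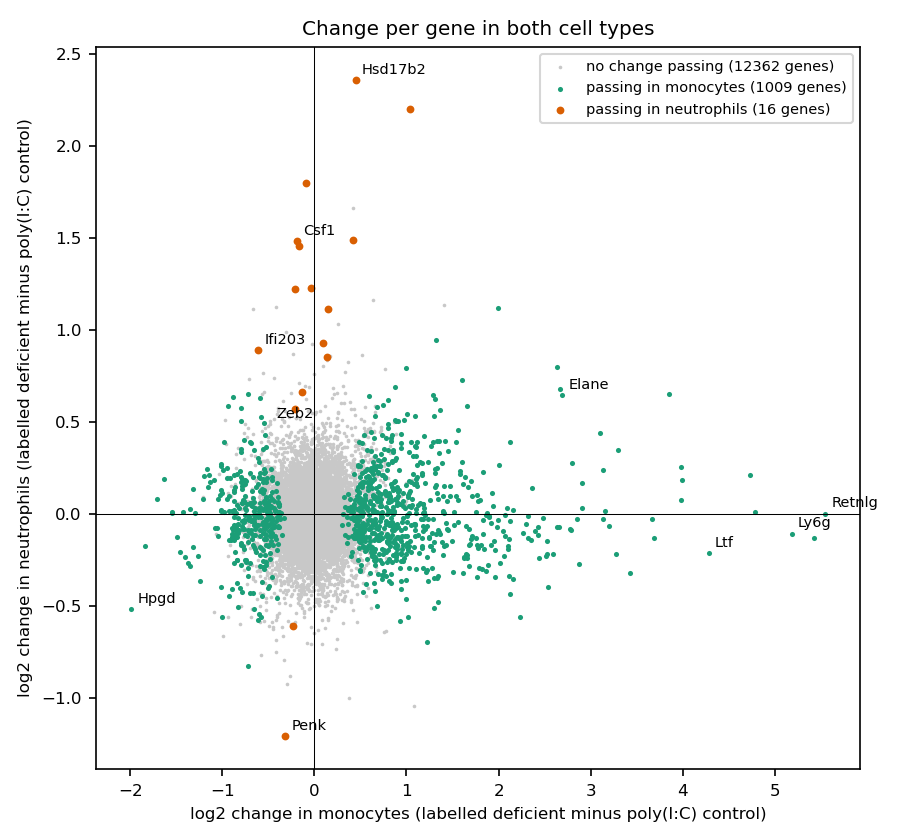
Log2 change per gene in monocytes (horizontal) and in neutrophils (vertical), labelled Zeb2-deficient minus poly(I:C) control, with the genes passing limma's threshold in monocytes alone (1009) and in neutrophils (16) coloured. The monocyte changes spread to 5.55 (Retnlg), while the neutrophil axis reaches 2.36 (Hsd17b2).

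The untreated control of each cell type was set beside the poly(I:C) controls as values, with no test. Interferon-stimulated genes lay 0.23 higher in the poly(I:C) monocytes and 0.21 higher in the poly(I:C) neutrophils by the median, at percentile 100 of 10000 random lists matched on expression in each. Against the set A controls alone, beside which the untreated arrays stand in the sample order, the medians were 0.11 (percentile 99.98) and 0.043 (percentile 62.6). Other lists reached percentile 100 too. In monocytes, primary granule genes lay 0.60 higher in the 4 poly(I:C) controls but at -0.083 against set A alone (percentile 13.2), and mature neutrophil genes 0.11 higher but at -0.18 against set A alone (percentile 0). In neutrophils, ribosomal proteins lay 0.14 and oxidative phosphorylation genes 0.18 higher, and 0.23 and 0.24 higher against set A alone, also at percentile 100. At least 2-fold differences numbered 23 genes in monocytes and 16 in neutrophils, while each poly(I:C) control set against the other controls gave 25 to 55 in monocytes and 16 to 31 in neutrophils.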

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

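The tests of the array set, of mature neutrophils or other cells in the monocyte sort, and of monocytes in the neutrophil sort were chosen only after the results were seen, as were the fits with the array set as a block or within a set. The counts over other splits of the arrays were planned before.

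The change differed between the cell types for 359 genes, a difference between groups tested directly. The genes with the smallest p were Ly6g (5.29), Retnlg (5.55), Chil1 (4.52), AA467197 (3.75), Stfa3 (4.77), Cldn1 (3.72), Cd24a (2.02), Ifit1bl2 (1.47), Il18rap (2.68) and Il1f9 (3.90), all higher in the monocyte change. List medians differed by 2.66 for mature neutrophil genes, 2.04 for primary granule genes, 0.34 for cell cycle, 0.45 for glycolysis and 0.38 for cholesterol synthesis. They differed by -0.67 for Ly-6C(hi) monocyte genes, -0.50 for interferon-stimulated genes, -0.33 for dissociation stress, -0.29 for inflammatory cytokines and -0.31 for conventional dendritic cell genes. With an estimated correlation the mature neutrophil list alone kept its call (adjusted p = 0.0198), the 9 others lay at 0.0906 to 0.380, and by fry 4 of the 10 kept theirs.

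Retnlg, Ly6g, Ltf, Elane and other granule genes rose in monocytes labelled Zeb2-deficient. A difference between the array sets is argued against as the whole cause, because each set held 2 arrays of each group and the rise was present inside both. The smallest change of a list's median per array was 2.14 (mature neutrophil list in set B, 95% interval 0.75 to 3.54), and the intervals of both granule lists lay above 0 in each set. Mature neutrophils in the monocyte sort are argued against as the sole source: 9 of 13 risen primary granule genes (Ctsg, Elane, Fcnb, Gfi1, Gstm1, Mpo, Ms4a3, Nkg7 and Prtn3, some chosen after their values were seen) lay above control monocytes and above neutrophils of the same label by limma. Of 30 genes at least 32-fold higher in control neutrophils, 36.67% lay within 2 SE of the rise predicted by 1 common share of neutrophils, 16.8%, the median share implied by the 10 list members among them. Open is a change within monocytes through loss of Zeb2 or through Mx1-Cre, which the controls lacked, and neither was tested. Immature granulocytic cells in the Ly-6C(hi) gate, which could carry these genes, are open too.

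Monocyte genes such as Tmem176b, Cx3cr1 and Ccl9 fell, and cells lacking monocyte genes in the sort could produce such a fall. Of 24 genes at least 32-fold higher in control monocytes, 91.67% lay within 2 SE of their median change of -0.65. All 24 lay below 0, from -1.54 (Ms4a4a) to -0.073 (S100a10), and 9 were called by limma. With SEs of 0.16 to 0.34 a band of 2 SE admits unequal falls, so the share does not show a common fall. By limma 0 genes fell by more than that median (28 of the 326 fallen genes at unadjusted p under 0.05). The adjustment ran over all 13387 genes and leaves little power, so the count of 0 does not show that the fall was uniform. The Zeb2 change of -0.48 lies within 1 SE (0.24) of the same median. Zeb2 differed less between the control cell types than these 24 genes, so this closeness cannot tell whether the same mixture lowered Zeb2. Lower expression in each monocyte, through loss of Zeb2 or through Mx1-Cre, could also lower these genes, and these values do not separate the explanations.

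Hsd17b2, Csf1, Egr2, Crip1 and 10 other genes rose in neutrophils labelled Zeb2-deficient, and monocytes in the neutrophil sort are argued against as a common source. The genes at least 32-fold higher in control monocytes had a median change of 0.0996 (SE 0.14) in neutrophils, against 1.01 predicted from Crip1. Of the 14 risen genes, 4 (Crip1, Ifi203, Pdlim1 and Tmsb10, the last chosen after its values were seen) were higher in control monocytes. Chance is not excluded for the count, because 2 of 35 splits gave as many genes, and an effect of Zeb2 loss on these genes remains untested, the Zeb2 level itself lying higher.

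For the count of 1010 genes in monocytes, 1 of 35 splits, the real one, gave as many, the smallest share that 35 splits can give. The highest other gave 499, the split by array set gave 66, and the highest of the 7 others parting 3 same-numbered pairs gave 0. The count is thus unlikely by chance assignment of these arrays, but chance is not excluded. Every other split mixed the 2 groups, which widens their spread, and the arrays may not be separate animals. For the 12 monocyte lists chance cannot be excluded, with 3 of 35 splits giving as many and a highest other of 14. The split by set gave 7 lists and the 7 comparable splits up to 11. For the 16 neutrophil genes it cannot, with 2 of 35 and a highest other of 160, which is the split by array set. That split gave several times the real count and so points to a structure of the samples; the values were 27 with the set as a block, 3 within set A and 14 within set B, and the 7 comparable splits gave up to 0. For the 4 neutrophil lists it cannot, with 12 of 35 and a highest other of 6, the 7 comparable splits giving up to 5.

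For the 359 genes differing between the cell types, 1 of 100 drawn splits, the real one, gave as many. The highest other gave 311, kept the real monocyte groups and was among the 6 others parting 6 pairs. The splits regrouped both cell types, and those that kept the monocyte groups and regrouped the neutrophils gave 249, 263 and 311. The count therefore rests mostly on the monocyte grouping, and chance in the neutrophil grouping is not excluded. For the 10 lists chance cannot be excluded, with 13 of 100 and a highest other of 14. For the 7846 genes and 12 lists of the control cell types, 1 of 35 splits gave as many of each, with highest others of 0 genes and 11 lists. Every other split mixed the cell types within its groups, which widens their spread, so 0 genes there was close to fixed in advance. Another split gave 11 lists, and 0 of the real lists passed with an estimated correlation, so chance is not excluded for the lists.

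Single arrays stood apart from the other 3 of their group by Dixon's ratio in 16 of 450 groups tested (3.56%), where chance marks about 1 in 20. In monocytes, control replicate 1 was highest for Zeb2 (10.08, next 9.88) and lowest for Gbp3 (6.62, next 7.11), and control replicate 4 was highest for Clec4b2 (5.75, next 4.75) and lowest for Marveld2 (3.62, next 3.76). Deficient replicate 2 was highest for Cd209a (5.06, next 4.54) and Egr2 (5.56, next 4.95) and lowest for Cd24a (10.76, next 11.45). In neutrophils, control replicate 1 was lowest for the dissociation stress list (7.68, next 7.99), the Ly-6C(hi) monocyte list (5.07, next 5.42) and Slc18a2 (5.42, next 5.79). Control replicate 2 was highest for Pkm (10.76, next 10.23) and lowest for Lgals3bp (4.74, next 5.11). Control replicate 4 was lowest for Penk (5.09, next 5.66) and highest for Mx2 (3.01, next 2.53), control replicate 5 was lowest for Hsd17b2 (4.54, next 4.77), and deficient replicate 3 was lowest for Ccl3 (8.61, next 9.67).

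Among 5017 probe sets without exactly 1 gene name, which the comparisons of genes do not use, 42 changed in monocytes, 36 up and 6 down, and 0 in neutrophils.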

How the results depend on the processing

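The fits with the array set as a block or within a set were chosen only after the data were seen. The other alternatives were planned.

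Of the values for comparisons as a whole, 254 stayed on the same side or within 1.5 times, 37 moved and 1 became stronger. Of those for single genes and lists, 8426 stayed the same, 405 became weaker, 156 stronger and 7 reversed. The number of arrays and the spread between them limit these counts, and settings with fewer arrays have less power by construction. For the other moves the cause was not tested.

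With only the arrays of the compared groups fitted, 500 genes changed in monocytes and 9 in neutrophils, and 7 neutrophil lists passed. Array weights gave 1613 genes in monocytes and 650 for the difference between cell types, and all 5 controls gave 551 for the difference. With the array set as a block the counts were 1749 genes in monocytes, 27 in neutrophils and 727 for the difference. Set A alone gave 215, 3 and 72. Set B alone gave 1724 genes in monocytes and 731 for the difference, 7 neutrophil lists, and a Zeb2 change in monocytes of -0.77 that passed the test (adjusted p = 0.0350). Stricter thresholds leave fewer genes by construction: at least 2-fold, 304 in monocytes, 10 in neutrophils and 2762 between control cell types; adjusted p under 0.01, 469 in monocytes, 9 in neutrophils and 152 for the difference.

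With the replicate number as a block, 8 neutrophil lists passed, and the block moved no other count by over 1.5 times. The genes called did turn over: it called 688 genes in monocytes, 596 of them among the 1010, and 11 in neutrophils, 10 of them among the 16. It ended 4 calls of named genes in monocytes and 5 in neutrophils, and brought 5 others past the threshold in monocytes. For the difference, genotype and number as a block called 407 genes, 307 of them among the 359. Among named genes that block ended the calls of Hsd17b7, Adgre4 and Hk3. It brought Fosb, Cx3cr1, Ms4a4c, Cd63, Nkg7 and Ms4a3 past the threshold. With an estimated correlation 1 list passed in monocytes, 0 in neutrophils, 1 for the difference and 0 between control cell types. By fry the counts were 0 in neutrophils, 4 for the difference and 26 between control cell types.

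Leaving out each array in turn gave 620 to 2001 genes and 10 to 14 lists in monocytes, 8 to 17 genes and 3 to 7 lists in neutrophils, 245 to 904 genes and 10 to 13 lists for the difference, and 7034 to 7440 genes and 10 to 12 lists between control cell types. Zeb2 ranged from -0.61 to -0.24 in monocytes and from 0.32 to 0.70 in neutrophils, and Pearson's r between the changes from 0.0209 to 0.0697.

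Reversed values were the oxidative phosphorylation list in neutrophils (0.040 in set B), and in set A the neutrophil changes of Ear6 (-0.23), Pf4 (-0.55), Ppbp (-0.17) and Cd3d (-0.15) and the difference between cell types for Rpl19 (0.085). Ear6 also reversed without neutrophil deficient replicate 4, and leaving out each array in turn it ranged from -0.015 to 0.39. The cause was not tested. The alternative of an offset for linear values was not run, because the values are on a log2 scale.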

Other observations

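The test of a shift between cell types across array sets, and the comparison of monocytes labelled Zeb2-deficient with control monocytes and with neutrophils labelled Zeb2-deficient, were chosen only after the results were seen.

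Of the 684 genes that rose in monocytes labelled Zeb2-deficient, 246 also lay above neutrophils labelled Zeb2-deficient by limma and above the mean of control neutrophils, including all 15 risen cell cycle genes and 0 of 20 mature neutrophil and secondary granule genes. Myb reached 8.19, against 7.10 in neutrophils labelled Zeb2-deficient. The proto-oncogene Myc, chosen after its values were seen, went from 6.29 to 7.83, against 4.84 in those neutrophils. The cell cycle kinase Cdk6, chosen after its values were seen, rose by 1.40.

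The share of neutrophil RNA that each gene alone would imply varied widely among the 30 genes at least 32-fold higher in control neutrophils, from 0.231% to 47.2%, with a median of 8.94%, and of 16.8% for the 10 members of the mature neutrophil list. The secondary granule gene Ltf implied 47.2% and Chil1 35.0%, Ly6g 15.6% and Cxcr2 7.79%. The gelatinase Mmp9 implied 2.51%, and Ptgs2 and Il1b, expressed in mature neutrophils, 0.356% and 0.231%.

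A shift of monocytes along the monocyte to neutrophil difference was tested with genes chosen in one array set and changes measured in the other. Of genes at least 4-fold higher in control neutrophils, 84.3% of 350 lay higher in the deficient monocytes of set B and 91.6% of 297 in those of set A, where 43.45% and 45.5% of all genes did. Of genes at least 4-fold higher in control monocytes, 70.24% of 504 and 80.4% of 470 lay lower. The lowest of these, 70.24%, lay between the limits written for the test, over 75% for a shift and under 60% against it, so a general shift and a change confined to some genes cannot be told apart.

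Among the control monocytes, set B lay above set A by a median of 0.95 for primary granule genes, 0.57 for mature neutrophil genes, 0.47 for dissociation stress and 0.26 for interferon-stimulated genes. Principal component 1 of the monocyte arrays held 56.2% of the variance, with deficient replicate 2 at 5.15, the other deficient arrays at -19.8, -33.0 and -48.0, and the controls at 9.79 to 26.2. The untreated monocyte array scored 23.4, against 23.5 and 26.2 in set A controls and 9.79 and 12.7 in set B controls. On component 1 of the neutrophil arrays the untreated array scored 13.7. The set A controls there scored 10.9 and 16.3 and the set B controls -7.57 and -7.17.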
